A study of Mus musculus with 4 samples.

How the data were processed

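Total RNA from whole lungs, pooled from 2 mice per genotype, was labelled with Cy3 and hybridised to Agilent single-colour arrays, per the labels' protocols. The 4 samples are wild type (female), Casp1-/-, Asc-/- and Nlrp3-/- (male), with 1 array each, grouped by the genotype in the labels. All 4 arrays lay on 1 slide, so no slide or scan block could be fitted. The deposited scanner files hold spot intensities on a linear scale made with Agilent Feature Extraction version 10.10.1.1, per the file headers, and the array design was annotated on build mm9. The processed signal in them is background-subtracted by that software, per the file headers. Flags deposited by the authors mark spots well above background, saturated spots and outliers, and no spot was saturated.

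The deposited value table of the same arrays holds intensities on a linear scale. Matched by spot number, each column equals the processed signal times 1 constant, 3.70 for wild type, 3.77 for Casp1-/-, 3.22 for Asc-/- and 4.22 for Nlrp3-/-. Column medians were 100.2, 105.2, 87.4 and 83.2 in that order. What the columns were scaled to stays unknown. Every column belonged to 1 sample.

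Of 62976 features, 59305 were not controls and carried 55681 different probes. Spots flagged as outliers were left out, between 171 and 201 per array, and spots of the same probe were averaged. A probe counted as well above background where over 50% of its spots did. Signals were log2-transformed and each array's 75th percentile over non-control spots was subtracted. The percentile stood at 337 for wild type, 345 for Casp1-/-, 372 for Asc-/- and 248 for Nlrp3-/-. Probes were named through unversioned RefSeq accessions in a gene table of assembly GRCm38.p6, used for names and neighbouring genes only because the builds differ: 26762 probes matched 20284 genes, and 28919 probes were not matched and are not analysed here.

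A measured fold is the mean over a gene's probes well above background on both arrays. For a gene above background on 1 array only, the fold is a bound, the bright signal over the higher of the other array's floor (its lowest signal well above background) and the probe's own signal; genes whose bounds disagree in direction were dropped. A gene counted at a fold of at least 2. Where several probes measured a gene past 2-fold, between 92.6% and 99.0% of genes had all probes in the same direction, depending on the contrast. For a division of the arrays, a gene counted where the lowest array of one side was at least 2-fold above the highest of the other, with probes above background on all 4 arrays first and floors otherwise. No hypothesis test is reported, since genes are not replicates. Fisher tests of the genes beside the targeted genes, none of which passed, and bootstraps over genes were run and dropped for this reason.

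Before the data were examined, 35 gene lists were fixed, covering pathways, lung and immune cell types, neighbouring tissues, the circadian clock and immediate early genes. The clock and immediate early lists were set as technical lists. The secretory airway mucosa list and the STAT6 and type 2 response list hold genes remembered from published work on these mice. Their medians and percentiles are therefore not independent evidence of a direction in any contrast. Each list is given by the median log2 fold of its measured genes and that median's percentile among 10000 random lists of equal size matched on expression in 20 bins, which describes these arrays only. Co-regulated genes make extreme percentiles common: against wild type 23, 23 and 24 of the 35 lists lay outside 2.5 to 97.5 in Casp1-/-, Asc-/- and Nlrp3-/-. Older symbols were updated through unique synonyms. Named genes were fixed by a rule: per contrast with wild type the 10 highest and 10 lowest measured folds (5 and 5 between knockouts), at least 2-fold, with probes in 1 direction and the brighter side at or above the array's median level, leaving out predicted genes, antigen receptor segments, Xist and Y-linked genes; up to 5 bounds per direction; up to 10 genes with the widest gaps per division; and up to 4 list members with the largest fold. Spdef, Tff2, Arntl and a few other list members outside these were named after their values were seen.

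Alternatives were normexp background correction (offset 50) in limma, quantile normalization, median centring, the submitters' value table, 2 other filters on dim probes and the brightest probe per gene. Normexp used median spot and background signals in place of the planned mean spot signal, which the files lack. This change and a run without the Nlrp3-/- array were chosen after seeing the data. The rules on outlier spots, repeated spots and disagreeing bounds were also set after the data were first read. Counts within 1.5 times were taken as the same, log2 values within the median spot SD times the square root of 2, and correlations within the sampling error of Fisher's z over genes, as tolerances and not tests. The shared-control correlation came from 100 simulated sets of arrays. The counting code was tested on simulated data for Asc-/- against wild type over 14721 genes: it found 100 of 100 genes planted at 3-fold, 0 of 100 planted at 1.5-fold and 0 others, which checks the code and not the precision between animals. R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.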

Results

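RNA abundance was measured in whole lungs of C57BL/6 mice, 9 weeks old, 24 h after intranasal infection with 5e+07 CFU of the bacterium Streptococcus pneumoniae. The lungs were perfused before collection. The 4 genotypes were wild type and mice without Nlrp3, Pycard (which encodes the adaptor Asc) or Casp1, the sensor, the adaptor and the protease of the NLRP3 inflammasome, a cytosolic complex that processes interleukin-1β and interleukin-18. Each genotype was measured on 1 single-colour array hybridised with RNA pooled from 2 mice, so every value below comes from 1 pool per genotype, no difference has a replicate check, and the number of arrays limits the precision. The wild-type pool was female and the 3 knockout pools were male, so genotype and sex cannot be told apart in any contrast with wild type. All 4 pools came from infected mice, so differences already present before infection cannot be told from differences in the response. Between 53.9% of probes (Nlrp3-/-) and 57.5% (Casp1-/-) were well above background, with 55.7% in wild type and 56.7% in Asc-/-. Repeated spots of the same probe within an array had a median SD of 0.07 on the log2 scale on each array, which covers spot error and neither labelling nor animals.

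The targeted genes were read first. The Casp1 probe gave a log2 fold of -1.98 in the Casp1-/- pool against wild type (3.95-fold lower), 0.43 in Asc-/- and 1.01 in Nlrp3-/-. The Pycard probe was lower by 87.1-fold in the Asc-/- pool (log2 fold -6.44), with -0.40 in Casp1-/- and 0.36 in Nlrp3-/-. In the Nlrp3-/- pool the Nlrp3 probes had log2 folds of -1.18 and -2.62, while in the other knockout pools both lay between -0.39 and -0.61. Each targeted gene was thus lowest in the pool labelled as its knockout. Whether these probes lie inside the deleted parts is not known here, and a probe outside them would check nothing. Xist, the non-coding RNA of X inactivation, was well above background in the wild-type pool only, while the Y-linked genes Ddx3y (at least 72.5-fold) and Eif2s3y (70.1-fold) were higher in the Casp1-/- pool than in wild type. These values fit the labelled sexes. Uty was above background in the 3 male pools on 1 of its probes, and Kdm5d was not well above background on any array.

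The contrast of Casp1-/- with wild type asked what differs in the infected lung without the effector protease. Dbp, a transcription factor driven by the circadian clock, was 6.02-fold higher, and Hlf, Nr1d1 and Per3 of the same list had log2 folds of 1.65, 1.58 and 1.28. Colq (6.33-fold), Arhgap6 (5.72-fold), Scube2 (4.50-fold) and Camp, the neutrophil peptide cathelicidin (3.83-fold), were also among the highest, whereas the neutrophil list as a whole had a median of -0.24, with 2 of 20 genes at least 2-fold higher and 1 lower. Clca1, a protein secreted by goblet cells, was 10.4-fold lower, and Ccl17, a chemokine for T helper 2 cells, was 4.90-fold lower. Plac9a, Myrip and Aldh1a3 had log2 folds of -2.21, -1.96 and -1.58.

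Among the fixed gene lists, 5 of the 14 measured circadian clock genes were at least 2-fold higher in the Casp1-/- pool and 0 were 2-fold lower (median log2 fold 0.66, percentile 100 of 10000 random lists matched on expression), while Arntl, a clock gene of opposite phase, had -0.88. Over the scalings the clock median ranged from 0.26 to 0.73. The secretory airway mucosa list had a median of -0.44, with 6 of 21 measured genes at least 2-fold lower, among them Retnlb (-1.38), Muc5ac (-1.31) and Fcgbp (-1.19). The STAT6 and type 2 response list had a median of -0.36 and 4 of 22 genes at least 2-fold lower, including Il1rl1, the interleukin-33 receptor (-1.68), and Alox15 (-1.37). Both of these lists hold genes remembered from published work on these mice and are not independent evidence of a direction. Cell cycle genes had a median of 0.51, which ranged from 0.27 to 0.57, with Top2a at 1.07. Club cell genes had a median of 0.39 and fibroblast and matrix genes 0.42, with Inmt at 1.15 and Eln at -1.20. Cardiac muscle genes had a median of -0.45, which ranged from -0.46 to -0.28 over the scalings, with Nppa at -1.33. Myh7, a myosin gene of cardiac and slow muscle outside the measured genes of this list, was 3.91-fold higher. The Asc-/- pool had similar medians against wild type, -0.52 for cardiac muscle and 0.37 for fibroblast and matrix genes. The Nlrp3-/- pool had 0.23 and -0.30 for these lists. Il17a (-1.42) and Il22 (-1.10), cytokines of type 17 lymphocytes, were the only 2 genes at least 2-fold lower on the list of neutrophil chemoattractants and acute cytokines, whose median was 0.10. In all, 348 genes were at least 2-fold higher and 291 at least 2-fold lower, of which 137 and 157 rest on bounds because the gene was well above background on 1 of the arrays only. Normexp background correction gave 82 higher and 77 lower, and no filter on dim probes 717 and 689. Olfactory and vomeronasal receptor genes made up 13.3% of the bounds and 0.290% of the measured genes past 2-fold.

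In the Asc-/- pool, genes of the secretory airway mucosa were lower than in wild type. Clca1 was 98.4-fold lower, Bpifa1, an abundant secreted airway protein, 14.9-fold, Reg3g, an antimicrobial lectin, 7.30-fold, Tff2, a trefoil peptide, 6.43-fold and Agr2, which folds mucins, 5.95-fold. Of the 21 measured genes of this list, 14 were at least 2-fold lower and 0 higher, with a median log2 fold of -1.50 at percentile 0 of the random lists, and Spdef, a transcription factor of goblet cells, had -1.18. Because the list holds genes remembered from published work on these mice, that percentile is not independent evidence of a direction. Hal, which degrades histidine, was 57.8-fold higher, Gdpd3, a phospholipid-cleaving enzyme, 39.2-fold, and Ctse, cathepsin E, 14.8-fold. Gdpd3 lies 59 genes from the targeted Pycard, and whether its fold comes from the loss of Asc was not tested. Tnnc2 and Acta1, a troponin and an actin of skeletal muscle, were 24.6-fold and 12.4-fold higher. The source of their folds was not tested.

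Further lists lay lower or higher in the Asc-/- pool. Ciliated cell genes had a median of -0.82, with 4 of 17 at least 2-fold lower (Sntn -1.20, Spag17 -1.06). Club cell genes had a median of -0.36, which ranged from -0.42 to -0.22 over the scalings, with Cyp2b10 at -1.25. The squamous and basal epithelium list did not stand apart, with a median of -0.13 at percentile 17.8 and 1 of 8 genes at least 2-fold lower. B and plasma cell genes had a median of -0.56, with Jchain at -1.99 and Cd79a at -1.76. Interferon gamma response and antigen presentation genes had a median of -0.46, with Ifng itself at -1.24. The STAT6 and type 2 response list had a median of -0.37, which ranged from -0.43 to -0.24 over the scalings, against 0.02 in Nlrp3-/-, which ranged from -0.23 to 0.15. Erythroid genes had a median of 1.36, and 5 of 7 were at least 2-fold higher, with Alas2 at 1.81 and Hbb-b2 at 1.65. Skeletal muscle genes had a median of 0.84, and 5 of 10 were at least 2-fold higher. In Casp1-/- and Nlrp3-/- the skeletal muscle medians were -0.03 and -0.24, and the erythroid medians 0.45 and 0.80. The skeletal muscle and erythroid lists were fixed as tissue lists. Whether more of these tissues entered the Asc-/- pool was not tested. Il17a (-1.69) and Il22 (-1.40) were again low. In all, 291 genes were at least 2-fold higher and 430 at least 2-fold lower, of which 102 and 168 rest on bounds. Centring each array on its median turned that split to 378 higher and 329 lower, and normexp background correction gave 87 and 125.

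The Nlrp3-/- pool stood farthest from wild type and held higher levels of inflammatory genes. Ptx3, a pentraxin of innate immunity, was 5.68-fold higher, Il10 5.26-fold, Camp 5.06-fold, Ifnb1, interferon beta, 4.94-fold, and Cx3cl1, the chemokine fractalkine, 4.39-fold. Hal was 17.8-fold higher, the heat shock gene Hspa1a 5.77-fold and Dio2, which activates thyroid hormone, 5.57-fold. Clca1 was 54.6-fold lower, Art4 14.1-fold, Cyp26b1, which degrades retinoic acid, 11.9-fold, Ogn, a matrix proteoglycan, 9.36-fold, and Adh1, an alcohol dehydrogenase, 8.72-fold. Lgi3, on the alveolar type 2 cell list, was 7.09-fold lower.

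By list, 11 of 22 chemoattractant and acute cytokine genes were at least 2-fold higher and 0 lower (median 1.0), including Il6 (2.04), Csf3 (1.83) and Ptgs2 (1.70). Of the type I interferon response genes, 11 of 24 were at least 2-fold higher (median 0.98, and at least 0.62 over the scalings), including Rsad2 (1.42) and Ifit2 (1.29), and of the interferon gamma response genes 10 of 24 (median 0.80), including Nos2 (1.98), Ifng (1.79) and Cxcl9 (1.77). Coagulation and tissue repair genes had a median of 0.83, with Il11 at 1.98, immediate early genes 0.91, with Atf3 at 1.83, and neutrophil genes 0.56, with Mpo at 1.73. The immediate early list was set as a technical list and not as an inflammatory pathway. Its median was also 0.83 against Casp1-/-, and -0.61 for Asc-/- against Nlrp3-/-. Over the scalings the coagulation median ranged from 0.45 to 0.85 and the neutrophil median from 0.31 to 0.57. Each of the 6 medians lay at or above percentile 99.9 of the random lists. The matched random lists themselves had medians above 0 in this contrast, from 0.13 (immediate early) to 0.27 (type I interferon), with 0.19 for neutrophil genes. Part of each median is thus shared by other genes of like expression. The inflammasome pathway list had a median of 0.49, with Casp4 at 1.13 and Il18 at 1.12, and ranged from 0.24 to 0.51 over the scalings.

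Several lists of airway, endothelial and lymphoid cells were lower in the same pool, while the monocyte and interstitial macrophage list lay within the random range (-0.08). The dendritic cell list had a median of 0.38, with 0 of 11 genes past 2-fold and quartiles of -0.37 and 0.51. That median ranged from 0.13 to 0.40 over the scalings. Against the male pools the list did not stand apart, with -0.01 against Casp1-/- and 0.08 for Asc-/- against Nlrp3-/-. Secretory airway mucosa genes had a median of -1.47, with 14 of 22 at least 2-fold lower (Itln1 -3.10, Muc5ac -3.08, Agr2 -2.82), although Spdef had -0.16. Ciliated cell genes had a median of -1.15, with 13 of 16 at least 2-fold lower, and club cell genes -0.84, with Cyp2f2 at -1.63. NK cell genes had a median of -1.09, with Klrb1c at -1.99, B and plasma cell genes -0.93, with Cr2 at -2.18. Over the scalings these medians ranged from -1.35 to -0.40 and from -1.19 to -0.46. Endothelial genes had a median of -0.70, with Tmem100 at -2.79 and Tek at -1.80. Adipose tissue genes had a median of -1.30, with Car3 at -2.63 and Adipoq at -2.14, and alveolar macrophage genes -0.63, with Siglecf at -1.71. Erythroid genes had a median of 0.80. In all, 771 genes were at least 2-fold higher and 919 at least 2-fold lower, of which 148 and 253 rest on bounds. The submitters' own scaling widened that split to 437 higher and 1476 lower, and normexp background correction turned it to 348 higher and 284 lower.

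**Figure D1:**
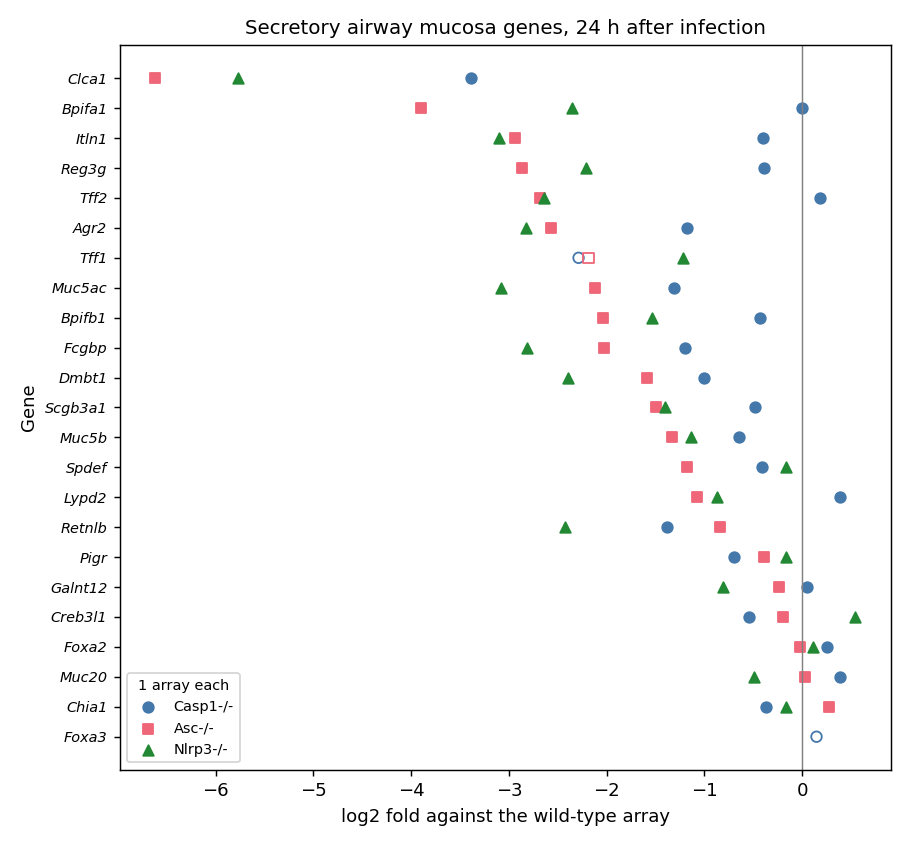
Log2 fold of each secretory airway mucosa gene (y axis) against the wild-type array in the Casp1-/- (circles), Asc-/- (squares) and Nlrp3-/- (triangles) pools, 1 array each; open markers are bounds. Clca1 lies at -3.38, -6.62 and -5.77, and Tff2 at 0.19, -2.68 and -2.64.

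The knockout pools were all male, so contrasts between them are free of the sex difference. Against Casp1-/-, 3 of the 5 lowest genes of the naming rule in the Asc-/- pool were secretory products, Bpifa1 (14.9-fold lower), Clca1 (9.43-fold) and Tff2 (7.31-fold), and the secretory list had a median of -0.81 with 9 of 21 genes at least 2-fold lower. Club cell genes had a median of -0.88 and ciliated cell genes -0.58 in that contrast. Hal was 169-fold higher, Tnnc2 38.0-fold, Gdpd3 32.3-fold and Ctse 27.4-fold. Circadian clock genes had a median of -0.77, which ranged from -0.90 to -0.48 over the scalings, with Dbp at -2.51. The counts were 356 genes at least 2-fold higher and 522 lower. Centring on the median gave 497 and 372, and the submitters' scaling 275 and 688.

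Against Casp1-/-, the Nlrp3-/- pool had Hal 52.0-fold, Ifng 6.62-fold and Aldh1a3 5.51-fold higher. Art4 (30.1-fold), Ogn (23.2-fold), Mamdc2 (22.0-fold), Hhip (17.0-fold) and Stmn2 (16.7-fold) were lower. Type I interferon response genes had a median of 1.21 (matched random lists 0.40), which ranged from 0.76 to 1.23 over the scalings. Of these genes, 19 of 24 were at least 2-fold higher. The secretory list had a median of -1.10, with 12 of 21 at least 2-fold lower (Tff2 -2.83, Itln1 -2.65) and Creb3l1 at 1.09. The secretory median ranged from -1.42 to -0.78 over the scalings. Club cell genes had a median of -1.47 and ciliated cell genes -0.91. In this contrast 1097 genes were at least 2-fold higher and 1337 lower, against 466 and 2289 under the submitters' scaling and 505 and 482 with normexp.

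Between Asc-/- and Nlrp3-/-, secretory genes had a median of -0.10 that ranged from -0.10 to 0.10 over the scalings. Single genes went both ways, with quartiles of -0.50 and 0.52, and 1 of 21 was at least 2-fold higher and 2 lower. Inflammatory genes were mostly lower in Asc-/-. Of the chemoattractant and acute cytokine genes, 17 of 22 were at least 2-fold lower and 1 higher (median -1.35). Of the interferon gamma response genes, 14 of 24 were at least 2-fold lower (median -1.16), with Ifng at -3.03. Samd9l was 25.7-fold lower in Asc-/-, and C5ar1, the complement C5a receptor, 9.78-fold. Gdpd3 (57.4-fold), Tnnc2 (27.8-fold) and Clec1a (13.1-fold) were higher in Asc-/-. Endothelial genes had a median of 0.86. The counts were 784 higher and 876 lower, which turned to 910 and 655 under quantile normalization, 1017 and 692 with median centring and 1166 and 580 under the submitters' scaling.

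The study's question of which inflammasome parts act alike was addressed by dividing the 4 arrays. In Asc-/- and Nlrp3-/- against wild type and Casp1-/-, 65 genes were lower in both, with every array of one side at least 2-fold from every array of the other, and 23 were higher. The widest measured gaps below were Cldn22 (7.18-fold), Tff2 (6.25-fold), Itln1 (6.18-fold), Clca1 (5.24-fold) and Bpifa1 (5.11-fold), followed by Sult1d1, Art4 and Reg3g. Hal had the widest gap above (17.8-fold), before Dera (3.79-fold) and Dao (3.09-fold). The other divisions by 2 and 2 separated fewer genes. Asc-/- and Casp1-/- shared 10 higher and 7 lower genes, with Il22, Nppa and Nppb among the lower ones, and Casp1-/- and Nlrp3-/- shared 7 and 7, with Camp and Ubd higher and Eln lower. The totals were 88, 17 and 14, or 53, 11 and 10 without bounds, 18, 2 and 4 with normexp background correction and 153, 89 and 57 with no filter on dim probes. With exchangeable arrays, each division by 2 and 2 would separate 33.3% of genes with no size threshold. That share cannot be set against the counts above, which use a 2-fold threshold, and no chance share at 2-fold was computed.

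All 3 knockout pools differed from wild type at 28 genes higher and 147 lower, of which 119 of the lower ones were bounds, led by Slc6a18 and Svs2, each above background on the wild-type array alone. Without bounds the counts were 16 and 28. A bound needs every array of the brighter side above background, which 1 array meets more easily than 3. Bounds were likewise at 127 genes higher and 6 lower for Casp1-/- alone, 78 and 8 for Asc-/- alone and 110 and 69 for Nlrp3-/- alone. The counts with bounds include Xist, Ddx3y and Eif2s3y, which follow the labelled sexes. Papln, Kif12 and Slc26a1 had the widest measured gaps above, with log2 values of 2.13, 2.07 and 1.76. Alone against the other 3 arrays, Nlrp3-/- stood apart at 811 genes, Casp1-/- at 213 and Asc-/- at 178, or at 632, 80 and 92 without bounds.

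Fold changes were also compared across the 13992 genes measured on all 4 arrays, which are not independent replicates. Contrasts with no array in common had a Pearson r of 0.326 (Asc-/- minus Casp1-/- with Nlrp3-/- minus wild type), 0.260 (Casp1-/- minus wild type with Asc-/- minus Nlrp3-/-) and 0.108 (Asc-/- minus wild type with Nlrp3-/- minus Casp1-/-). Their covariances, 0.0871, 0.0557 and 0.0314, are tied by construction. The first is the sum of the others for any data, so the values are not separate pieces of evidence. Against the shared wild-type array, r was 0.319 for Asc-/- with Nlrp3-/-, 0.329 for Casp1-/- with Asc-/- and -0.038 for Casp1-/- with Nlrp3-/-. Spot noise alone, simulated with a shared array, gave r of 0.5 and a covariance of 0.0051. The covariances observed were 0.0790, 0.0476 and -0.0081. The wild-type pool's own animals and labelling enter each of these contrasts and are not in the simulation, so the values do not separate a shared knockout effect from the shared pool.

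**Figure D2:**
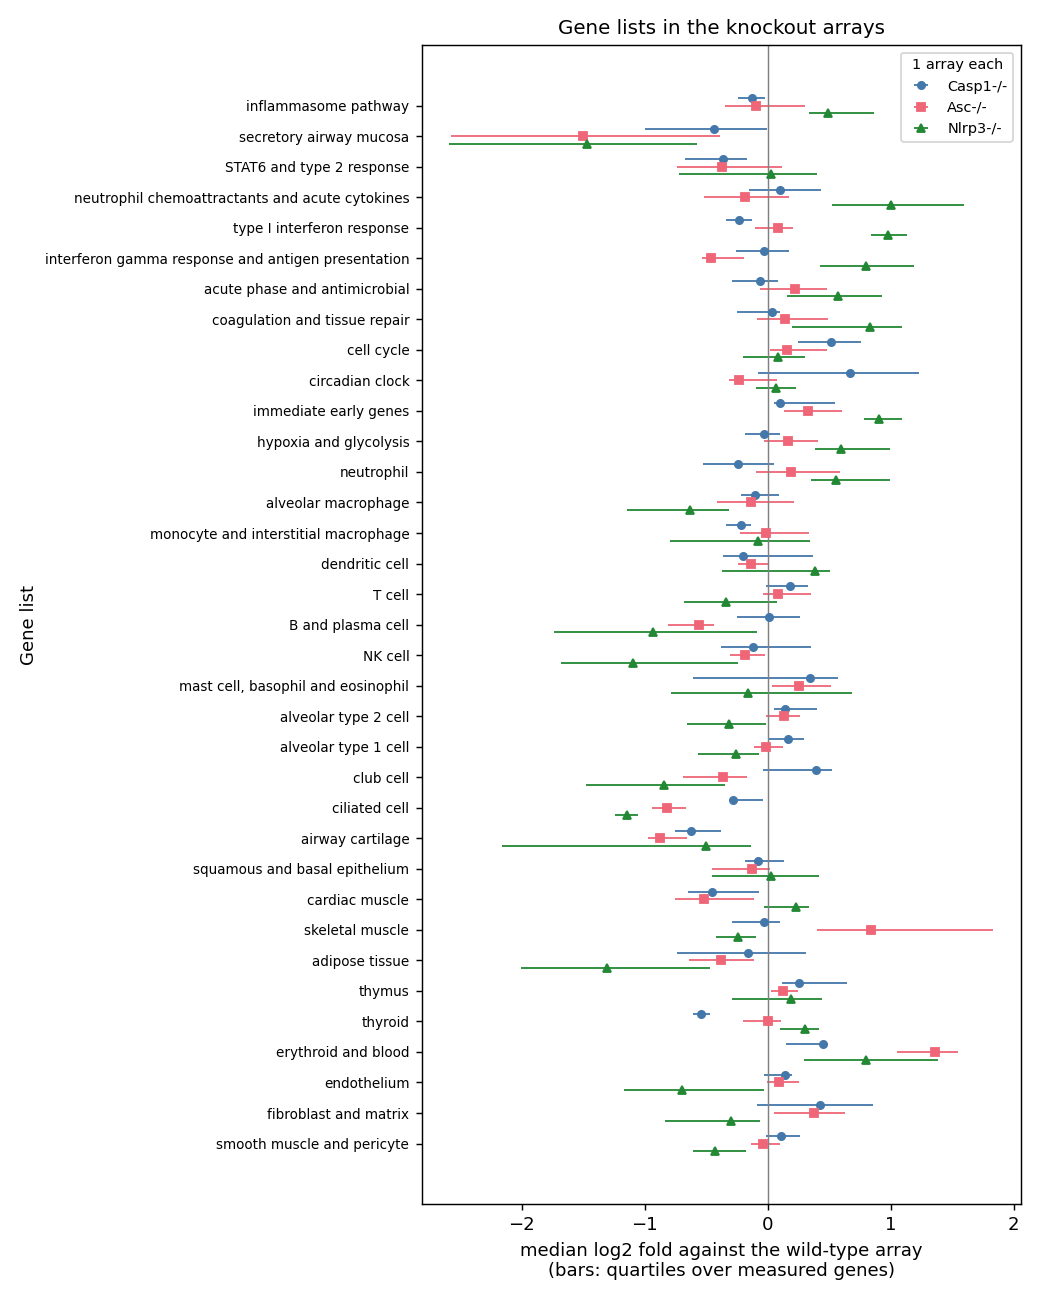
Median log2 fold against the wild-type array (x axis) of each of the 35 gene lists (y axis) in the 3 knockout pools, 1 array each; bars span the quartiles over measured genes. The secretory list lies at -0.44, -1.50 and -1.47 in Casp1-/-, Asc-/- and Nlrp3-/-, and the cytokine list at 0.10, -0.18 and 1.0.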

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

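The normexp run, which departs from the planned one in its signal, and the run without the Nlrp3-/- array were chosen after seeing the data, and the other alternatives before; no paired analysis was possible because each group holds 1 array, and the slide could not be fitted as a block. Quantile normalization, median centring and the brightest probe per gene kept each count of genes within 1.5 times, and none of the 90 log2 folds named by the rule changed direction where measured. Their sizes did change. Past the tolerance, 83 of the 90 moved with normexp, 50 with the submitters' table, 40 with median centring and 18 with quantile normalization. With the brightest probe per gene 4 moved, and with no filter on dim probes 8. Over the scalings, the secretory median against wild type ranged from -1.56 to -1.31 in Asc-/- and from -1.78 to -1.35 in Nlrp3-/-, and in Nlrp3-/- the cytokine median from 0.69 to 1.02 and the endothelial median from -0.95 to -0.58. Several medians varied by more than 1.5 times, among them NK cell (-1.35 to -0.40), B and plasma cell (-1.19 to -0.46), T cell (-0.59 to -0.15), neutrophil (0.31 to 0.57), coagulation and tissue repair (0.45 to 0.85), hypoxia and glycolysis (0.34 to 0.61) acute phase (0.18 to 0.59) and inflammasome pathway (0.24 to 0.51) in Nlrp3-/-, skeletal muscle in Asc-/- (0.50 to 0.98) and circadian clock (0.26 to 0.73), cell cycle (0.27 to 0.57) and airway cartilage (-0.63 to -0.12) in Casp1-/-. The normexp offset of 50 exceeds each array's median processed signal, which lay between 19.7 and 27.95. Adding such a constant makes the folds of dim spots smaller, and so lowers the counts. Normexp also started from median spot and background signals, so signal, correction and offset changed together and their shares were not tested. It gave 82 higher and 77 lower genes for Casp1-/-, 87 and 125 for Asc-/- and 348 and 284 for Nlrp3-/- against wild type, 123 and 147 for Asc-/- and 505 and 482 for Nlrp3-/- against Casp1-/-, and 274 and 410 for Asc-/- against Nlrp3-/-; its divisions held 18 (Asc-/- with Nlrp3-/-), 2 (Asc-/- with Casp1-/-), 4 (Casp1-/- with Nlrp3-/-), 40 (all knockouts), 49 (Casp1-/- alone), 53 (Asc-/- alone) and 309 genes (Nlrp3-/- alone). The submitters' table gave 437 and 1476 for Nlrp3-/- against wild type, 466 and 2289 against Casp1-/-, and 580 genes lower in Asc-/- than Nlrp3-/-, since it shifts all genes: the median over genes moved from 0.06 to -0.19 for Nlrp3-/- against wild type, from 0.10 to -0.21 against Casp1-/-, from -0.02 to 0.17 for Asc-/- against Nlrp3-/- and from 0.04 to -0.08 for Asc-/- against Casp1-/-. Median centring moved it to 0.17 for Asc-/- against wild type, 0.19 against Casp1-/- and 0.10 against Nlrp3-/-, and quantile normalization to -0.01 for Nlrp3-/- against Casp1-/-. With only probes above background on all 4 arrays, and so no bounds, counts were 160 and 109 for Casp1-/- and 170 and 223 for Asc-/- against wild type, 217 and 285 for Asc-/- against Casp1-/-, and 53, 11, 44, 80 and 92 for the divisions Asc-/- with Nlrp3-/-, Asc-/- with Casp1-/-, all knockouts, Casp1-/- alone and Asc-/- alone. With no filter they were 717 and 689, 563 and 936, and 1171 higher for Casp1-/-, Asc-/- and Nlrp3-/- against wild type, 593 and 972 for Asc-/- against Casp1-/-, 1386 lower in Asc-/- than Nlrp3-/-, and 153, 89, 57, 355, 387 and 310 for the divisions in the order above, leaving out Nlrp3-/- alone; the 3 correlations without a shared array were 0.177, 0.154 and 0.025. Without the Nlrp3-/- array, which leaves fewer arrays to part, the divisions held 329 (Asc-/- against wild type and Casp1-/-), 234 (Asc-/- and Casp1-/- against wild type) and 270 genes (Casp1-/- against wild type and Asc-/-). Among list medians past the random lists, 3 changed sign: inflammasome pathway in Asc-/- against wild type (0.0453 with median centring), cell cycle in Asc-/- against Nlrp3-/- (-0.0001 with normexp) and airway cartilage in Nlrp3-/- against Casp1-/- (0.36 with no filter); the cause was not tested. Signal over background limits the rest, since between 53.9% and 57.5% of probes per array were well above it.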

Other observations

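All the tests below and their criteria were chosen after the results were seen. Several groups of genes were not described above. Hypoxia and glycolysis genes had a median log2 fold of 0.59 in the Nlrp3-/- pool against wild type, with Slc2a1, a glucose transporter, at 1.44 and Adm, adrenomedullin, at 1.42, and medians of -0.03 in Casp1-/- and 0.17 in Asc-/-. Acute phase and antimicrobial genes had medians of -0.06, 0.22 and 0.57 in Casp1-/-, Asc-/- and Nlrp3-/-, with Pglyrp1, a peptidoglycan recognition protein, at 1.56 in Asc-/-. T cell genes had medians of 0.18, 0.08 and -0.34 in the same order, with Cd247 at -1.32 in Nlrp3-/-. Monocyte and interstitial macrophage genes had -0.22, -0.02 and -0.08, with Ccr2 at 1.20 in Asc-/- and Cx3cr1 at -1.71 in Nlrp3-/-, and dendritic cell genes -0.20, -0.14 and 0.38. Mast cell, basophil and eosinophil genes had 0.34, 0.25 and -0.16, with Prg2 at -1.46 in Casp1-/-. Alveolar type 2 genes had 0.14, 0.14 and -0.31, alveolar type 1 genes 0.17, -0.02 and -0.26 with Cav1 at -1.86 in Nlrp3-/-, and smooth muscle and pericyte genes 0.11, -0.04 and -0.43. Over the scalings the Nlrp3-/- medians of these 3 lists ranged from -0.57 to -0.30, from -0.61 to -0.24 and from -0.68 to -0.41. Airway cartilage had -0.62, -0.87 and -0.50 over 5, 6 and 5 measured genes (from -0.75 to 0.05 over the scalings in Nlrp3-/-), thymus 0.25, 0.12 and 0.19 over 5 of 12 genes, and thyroid -0.54, 0.01 and 0.31 over 4, 3 and 4 of 11 genes. Genes beside the targeted gene stood at least 2-fold apart from the other 3 arrays at 1 of 105 neighbours of Casp1 in Casp1-/- (0.952%, against 0.562% of other genes), 2 of 200 of Pycard in Asc-/- (1% against 0.645%, among them Gdpd3) and 8 of 200 of Nlrp3 in Nlrp3-/- (4% against 4.52%). These shares do not show the source of a single gene's fold, such as that of Gdpd3.

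Secretory genes were lower in both the Asc-/- and the Nlrp3-/- pool, on a list that holds genes remembered from published work on these mice. Sex argues poorly as the whole source, since against the male Casp1-/- pool the median was still -0.81 in Asc-/- and -1.10 in Nlrp3-/- (nearest 0 over the scalings -0.67 and -0.78), but it stays open for the part shared with Casp1-/- (-0.44 against wild type). Less proximal airway tissue in these pools cannot be told apart from lower expression: the secretory median lay only -0.23 from the ciliated median against Casp1-/- in Asc-/-, club and ciliated genes were lower too, while the squamous and basal list was not (medians 0.04 in Asc-/- and -0.03 in Nlrp3-/- over 8 genes that went both ways), and only 4 to 5 cartilage genes were measured. Club genes were higher in Casp1-/- itself (0.39), and against wild type the secretory median in Asc-/- lay further down, -0.68 from the ciliated and -1.14 from the club median, with overlapping quartiles. In Nlrp3-/- it lay -0.32 from the ciliated and -0.63 from the club median against wild type. Against Casp1-/-, the secretory median in Nlrp3-/- lay -0.19 from the ciliated median but 0.37 above the club median. In Asc-/- it lay 0.07 above the club median in that contrast. The loss of Asc and of Nlrp3 stays open as untested, and several pools per genotype of the same sex would be needed to test it.

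Cytokine and interferon genes were higher and endothelial genes lower in the Nlrp3-/- pool. The scaling of the array is unlikely to be the whole source, since under quantile normalization the lowest of the 3 cytokine and interferon medians was 0.55 and the endothelial median -0.81. Dilution of endothelial RNA by incoming neutrophils stays open. Neutrophil genes were higher (0.56, against 0.19 for matched random lists). The alveolar and smooth muscle genes lay 0.39 above the endothelial median with overlapping quartiles. Sex argues poorly as the whole source, since against the male Casp1-/- and Asc-/- pools the one nearest 0 of these medians was still 0.84 (type I interferon, Asc-/- against Nlrp3-/-, which lay between -0.84 and -0.49 over the scalings), and the endothelial median -0.75. A heavier infection in these 2 mice and the loss of Nlrp3 also stay open as untested. A technical source was not tested either, and the technical list of immediate early genes was higher in this pool too (0.91).

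Circadian clock genes differed in the Casp1-/- pool. The median of 7 daytime-output genes, such as Dbp, lay 1.84 above that of 3 genes of the opposite phase, such as Arntl, against wild type, which is consistent with lungs collected at another time of day. Sex alone argues poorly, since the same difference was -0.46 in Asc-/- and -0.21 in Nlrp3-/-, both male. An effect of Casp1 loss on the clock stays open, because collection times are not given in the sources used here.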
